A study of Mus musculus with 27 samples.

How the data were processed

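Livers of C57Bl/6 mice were examined 10 days after injection of AAV8, per the labels, with 27 samples in all. RNA was sequenced in 17 liver samples and chromatin in 10 samples, made up of 2 HA ChIP samples from HA-nSREBP1c livers, 3 HDAC3 ChIP samples from GFP livers, 3 HDAC3 ChIP samples from HA-nSREBP1c livers and 2 inputs. The labels number the RNA samples as replicates of injected mice without stating that each is 1 mouse, so p-values measure the spread between samples, which are called livers in the text. The table's numbering of libraries differs from the sample titles in several groups, so only the single knockouts and 2 HDAC3-floxed controls were tied to a numbered sample, and the other columns were used by group.

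The deposited RNA table holds whole-number read counts per RefSeq transcript, which the authors did not normalize, as the values themselves show. Bowtie, HOMER, edgeR and the genome build mm9 are named in the submitters' processing notes, and the aligner and counter of the RNA reads are not given in the sources used here. The log2 fold changes of each knockout against GFP in the deposited table come from the authors' edgeR comparison, per the file headers. The FDR values beside them are the authors' own, per the file headers, and are used here only to count their calls. A second set of 17 columns of per-sample values was not used. The deposited peak lists give positions of intervals of 200 bp on mm9, per the submitters' processing notes, with no score. Whether replicates were pooled for peak calling is not given in the sources used here. No input or per-replicate ChIP signal was used here.

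Of 28644 transcripts in the table, the authors marked 1 per gene, and these 22869 were used, with 5775 left out. They held 80.4 to 82% of all counts. Of 3705 genes with several transcripts, 802 had identical counts in each, and the smallest total was a median of 98.5% of the largest (lower quartile 86.7%). All 30 pairs of libraries within groups differed beyond sampling noise, with chi-square per degree of freedom from 2.859 to 40.94, over genes with a summed count of at least 20.

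Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter (12009 genes passed) and quasi-likelihood F-tests on 1 fit of the 4 groups, with a median of 5.8 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were HDAC3 LKO, SCAP LKO and Double LKO against the 6 GFP controls, Double LKO against each single knockout, and the contrast of the double knockout with the sum of the single ones on the log2 scale. The 6 controls of 3 floxed lines formed 1 group because the submitters' design text names GFP-injected mice as the controls. CPM (counts scaled to library size) are TMM-scaled, and log2 values per library for principal components used a prior count of 2. The first 3 principal components held 23, 19.4 and 10.8% of the variance. Adjusted p-values of single genes in the text are from edgeR unless another tool is named. The SE of a log2 fold change was worked back from the F-test, as its absolute value over the square root of F. It is an approximate measure.

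Gene lists were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. There were 31 lists of 581 genes, of which 579 were found in the table, 6 by a synonym in a RefSeq table of assembly GRCm38.p6, and 496 were tested. The 29 lists with at least 4 tested members entered the tests. They cover cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation, lipid droplets, lipoproteins, phospholipids, sphingolipids, gluconeogenesis and glycolysis, bile acids, the clock, the NCoR and HDAC complex, SREBP processing, the unfolded protein and integrated stress response, NRF2, p53, cell cycle, acute phase, inflammatory cytokines, markers of hepatocytes, macrophages, lymphocytes, neutrophils, stellate, endothelial, cholangiocyte, fetal and erythroid cells, xenobiotic metabolism, and male-biased, female-biased and Y-linked genes. Lymphocyte and neutrophil markers had 1 tested member each and were not tested as lists.

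The lists, tests, comparisons and rule for named genes were set before the data were examined. Named were Hdac3 and Scap; for each knockout against control the 10 called genes with the highest and the 10 with the lowest log2 fold change, with log2 CPM of at least 1 and no overlap between the groups; 5 of each for the other comparisons; and up to 4 members of each list with the lowest p, with the most highly expressed member that did not pass. Genes with provisional names were skipped, and some genes that the rule names are not used here. Genes outside the rule that are named for their difference between control lines or libraries were chosen after their values were seen.

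Overlap of calls between comparisons that share controls was set beside 20 simulations of unchanged groups against shared simulated controls, independent lists, and 8 splits of the controls. Peak lists were compared by overlap of at least 1 bp, with 95% exact binomial (Clopper-Pearson) intervals from scipy 1.17.1 under Python 3.11.15, which cover counting error only, and 100 shuffles of peaks within chromosomes. Figures were drawn with matplotlib 3.10.9.

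The fit was tested on counts simulated from the depths, control means and dispersions of these libraries, with 200 genes changed by 1.5-, 2- and 4-fold. For HDAC3 LKO against control (11851 genes) 41.2, 79.2 and 100% of changed genes were called, with 2 unchanged genes called. For SCAP LKO against control (11857 genes) these were 47.5, 76.2 and 100%, with 9 unchanged genes called. For Double LKO against control (11857 genes) they were 48.4, 80.6 and 98.4%, with 11. For Double LKO against HDAC3 LKO (11858 genes) they were 43.8, 82.4 and 93.9%, with 10. For Double LKO against SCAP LKO (11891 genes) they were 30.6, 77.6 and 94.3%, with 9.

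Alternatives were RLE normalization, no filter on low counts, DESeq2 1.42.0, only the groups compared, genotype-matched controls, a replicate block, leaving out each library, an estimated correlation or fry for lists, split controls for the overlap, and a reciprocal overlap of 50% for peaks. Limma voom with library quality weights, the numbered libraries without a block, and list counts without Double LKO library 2 or SCAP LKO replicate 4 were added after seeing the data.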

Results

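Gene expression was measured by RNA sequencing in livers of C57Bl/6 mice 10 days after injection of an adeno-associated virus of serotype 8, a vector that delivers genes to hepatocytes. Floxed mice received Cre recombinase, which removes the floxed gene, or GFP as control. No mice given Cre without a floxed gene were among the samples. An effect of Cre itself therefore cannot be told apart from gene loss within any single comparison with the GFP controls. In comparisons between knockouts both sides received Cre. HDAC3 is the histone deacetylase of the NCoR and SMRT corepressor complexes. SCAP is the escort protein that SREBP transcription factors need in order to be processed to their active nuclear form. There were 4 livers lacking HDAC3 (HDAC3 LKO), 4 lacking SCAP (SCAP LKO), 3 lacking both (Double LKO) and 6 GFP control livers, 2 from each floxed line. HDAC3 and an HA-tagged nuclear form of SREBP1c (HA-nSREBP1c) were also mapped on the genome by chromatin immunoprecipitation and sequencing (ChIP-seq).

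The RNA libraries held 4747602 to 19316642 counts over genes in the GFP controls, 5158695 to 8672408 in HDAC3 LKO, 3546597 to 7788828 in SCAP LKO and 3736618, 9761092 and 20622671 in Double LKO livers. Of 22869 genes in the table, 12009 had enough counts to be tested. The 3 Double LKO libraries carry the numbers 2, 3 and 4 in the table and are named so here. Library 2, the shallowest of them, stood apart on the second principal component of all libraries (45.8, against 1.6 and 8.7 in libraries 3 and 4). SCAP LKO replicate 4 was the next highest at 25.7.

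Hdac3 and Scap transcripts were lower in the livers labelled as lacking them. Hdac3 was at 36.9 ± 2.26 CPM (counts scaled to library size; mean ± SD, n = 6) in control livers, 9.59 ± 1.47 (n = 4) in HDAC3 LKO, 39 ± 2.19 (n = 4) in SCAP LKO and 11 ± 1.64 (n = 3) in Double LKO livers. It fell by 1.95 on the log2 scale in HDAC3 LKO (SE 0.11, adjusted p = 2.4e-09) and by 1.71 in Double LKO (SE 0.11, adjusted p = 4.78e-09), and its log2 difference in SCAP LKO was 0.07 (SE 0.09, adjusted p = 0.86). Scap was at 118 ± 17.2 CPM in control livers, 142 ± 10.5 in HDAC3 LKO, 51.4 ± 6.24 in SCAP LKO and 47.6 ± 2.82 in Double LKO livers, with the same numbers of livers. It fell by 1.21 in SCAP LKO (SE 0.11, adjusted p = 6.46e-07) and by 1.31 in Double LKO (SE 0.12, adjusted p = 6.31e-07), and its log2 difference in HDAC3 LKO was 0.27 (adjusted p = 0.0985). Every knockout library lay below every control library for its targeted gene, with 7.46 to 12.4 CPM of Hdac3 against 34.3 to 40.7, and 43.9 to 59 of Scap against 91.2 to 139.

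**Figure D1:**
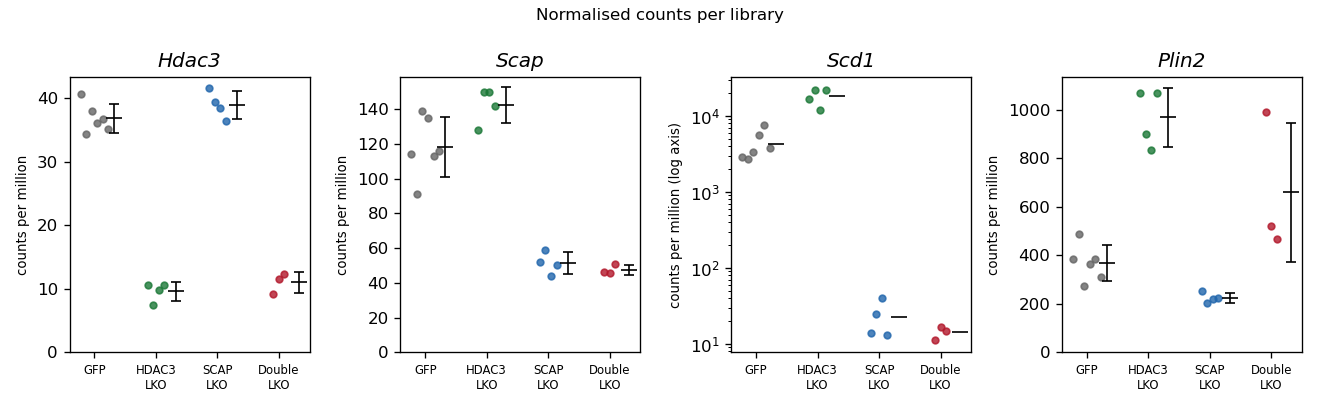
CPM of Hdac3, Scap, Scd1 (log axis) and Plin2 in each RNA library of the GFP control, HDAC3 LKO, SCAP LKO and Double LKO groups. Points are libraries, lines are group means and bars are SDs (mean only for Scd1). Hdac3 averaged 9.59 in HDAC3 LKO and 11 in Double LKO livers against 36.9 in controls, and Scd1 fell from 4340 in controls to 22.8 in SCAP LKO and 14.3 in Double LKO livers.

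Loss of HDAC3 raised 16 of 24 measured genes of lipid droplets and triglyceride storage. It also raised 17 of 29 genes of fatty acid oxidation and 8 of 19 of fatty acid synthesis, but as lists these did not pass with an estimated correlation (camera adjusted p = 0.169 and 0.232). Among lipid storage genes, Plin2, a coat protein of lipid droplets, rose by 1.40 on the log2 scale (SE 0.18, adjusted p = 3.9e-05). Scd1, the desaturase that makes monounsaturated fatty acids, rose by 2.08 (SE 0.305, adjusted p = 0.000145), from 4340 ± 1930 (n = 6) to 18300 ± 4820 CPM (n = 4). Most genes of cholesterol synthesis did not pass the test. In all, 946 genes were higher and 720 lower in HDAC3 LKO than in control livers (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 234 of these 1666 changed at least 2-fold.

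Of 24 measured lipid droplet and triglyceride storage genes, 16 rose and 8 did not pass in HDAC3 LKO livers, and 17 rose when adjusted over the list alone (camera adjusted p = 9.26e-11, fry adjusted p = 1.78e-06). This list held with an estimated correlation (adjusted p = 0.00705). Examples are Gpd1, which makes glycerol 3-phosphate (log2 fold change 1.20), Pnpla2, the adipose triglyceride lipase (0.87), and the monoglyceride lipase Mgll (0.66). Dgat2, the most highly expressed member that did not pass, was at 0.11 (adjusted p = 0.643). Of 29 fatty acid oxidation genes and targets of PPARa, 17 rose and 12 did not pass, with 18 rising when adjusted over the list alone. Ehhadh of the peroxisomal pathway rose by 1.68, the acyl-CoA dehydrogenase Acadm by 0.91 and Cpt1b, a carnitine palmitoyltransferase better known from muscle, by 1.75. The camera call of this list (adjusted p = 3.19e-11) was lost with an estimated correlation (adjusted p = 0.169), and fry gave an adjusted p of 0.000328. Of 19 fatty acid synthesis genes, 8 rose and 11 did not pass, with 9 rising when adjusted over the list alone. Besides Scd1 these were led by the elongases Elovl5 (1.61) and Elovl6 (1.28) and by Acacb (1.99), an acetyl-CoA carboxylase, while Fasn, the fatty acid synthase, was at 0.58 (adjusted p = 0.105). This call too (camera adjusted p = 0.000154) was lost with an estimated correlation (adjusted p = 0.232), and fry gave 0.004.

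Cholesterol synthesis and uptake genes moved little in HDAC3 LKO livers and in both directions. Of 24 genes, 2 rose, 6 fell and 16 did not pass, and 2 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.101, fry adjusted p = 0.066). Lss, the lanosterol synthase, fell by 0.39 and Mvk, the mevalonate kinase, by 0.57. The call of Mvk was lost without HDAC3 LKO replicate 2 (-0.52, adjusted p = 0.0623) and that of Lss with the replicate block (-0.45, adjusted p = 0.0598). Insig2, a protein that retains SCAP in the endoplasmic reticulum, rose by 1.69 (SE 0.20, adjusted p = 2.19e-05) and was the 1 called member among 10 genes of the SREBP processing machinery.

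Some genes of the clock and of the corepressor complex itself also changed. Of 18 clock genes, 3 rose, 2 fell and 13 did not pass, with 3 rising and 4 falling when adjusted over the list alone (camera adjusted p = 0.955; its median change is -0.13 and its mean 0.07). Arntl, which encodes the activator BMAL1, rose by 2.18 (SE 0.24, adjusted p = 1.22e-05) and Clock by 0.71, and Per2 fell by 0.62. Among 12 NCoR and HDAC complex genes, Tbl1xr1 (1.18), Hdac5 (0.80) and Tbl1x (0.63) rose and 2 fell, one of them Hdac3 (camera adjusted p = 0.862). Of 17 genes of the constitutive androstane receptor and xenobiotic metabolism, 8 rose and 9 did not pass, with 8 rising and 1 falling when adjusted over the list alone. Among them Ugt1a1, which conjugates bilirubin, rose by 0.65, and Cyp2c38 (2.02) and Cyp2a5 (1.21) belong to families of similar genes that can share reads. This list's camera call (adjusted p = 0.000164) was lost with an estimated correlation (adjusted p = 0.232), and fry gave 0.00305. Of 23 NRF2 and oxidative stress genes, 10 rose, 1 fell and 12 did not pass, in the same numbers over the list alone, with G6pdx, the entry enzyme of the pentose phosphate pathway, at 1.09 and the glutathione transferases Gstm4 at 0.94, Gstm2 at 1.17 and Gsta2 at 1.81, which again share sequence. The call of this list (camera adjusted p = 1.98e-05) was lost in the same way (adjusted p = 0.232 with an estimated correlation), and fry gave 0.00305.

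The genes with the highest fold changes and no overlap between HDAC3 LKO and control libraries included the monocarboxylate transporter Slc16a5 (log2 fold change 2.96, from 9.18 ± 1.96 to 71.4 ± 12.3 CPM), the steroid hydroxylase Cyp17a1 (2.35), Clstn3 (2.29) and Cdcp1 (2.32). Orm3 (3.03), Cyp2c40 (2.87), Gsta1 (2.87), Ugt2b37 (2.85), Tuba8 (2.58) and Tubb2a (2.22) completed this group and have near-identical relatives, so their values are uncertain. Without HDAC3 LKO replicate 3, Orm3 was at 2.37 and still called, but with the replicate block on numbered libraries it was at 0.65 and not called (adjusted p = 0.264). Among the most reduced were the NADPH oxidase Nox4 (-2.10, from 51.4 ± 5.13 to 12 ± 2.13 CPM), the steroid dehydrogenase Hsd3b5 (-2.68), Col27a1 (-2.19), Capn3 (-2.48), Cspg5 (-3.16), Pcp4l1 (-2.39) and Rec8 (-1.87). Scara5, a ferritin receptor, was the most reduced (-4.42), and it also differed between control lines, at 18.7 CPM in HDAC3-floxed against 2.26 in SCAP-floxed controls. With only the 2 HDAC3-floxed controls 839 genes passed, where Cdcp1, Orm3 and Gsta1 did not (log2 fold changes 1.63, 2.34 and 3.42, adjusted p = 0.0759, 0.0509 and 0.0871). Without HDAC3 LKO replicate 4 there were 1086. Gsta1 was also lost without HDAC3 LKO replicate 2 or 4 (adjusted p = 0.0668 and 0.0511). HDAC3 LKO replicate 2 was apart from the other 3 livers in Gpd1 (587 CPM against 893 to 943), Tbl1xr1 (149 against 181 to 185) and Mvk (13.6 against 15.5 to 16).

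Loss of SCAP lowered the genes of cholesterol synthesis and most measured genes of fatty acid synthesis. All 24 measured cholesterol synthesis and uptake genes fell, with a median log2 change of -2.08. Scd1 fell by 7.56 on the log2 scale (SE 0.45, adjusted p = 1.42e-09), from 4340 ± 1930 (n = 6) to 22.8 ± 12.5 CPM (n = 4), and Fasn by 3.53 (SE 0.27, adjusted p = 5.97e-08). In all, 143 genes differed between SCAP LKO and control livers (edgeR quasi-likelihood test, adjusted p under 0.05), 31 higher and 112 lower, of which 71 changed at least 2-fold.

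All 24 cholesterol genes also fell when adjusted over the list alone (camera adjusted p = 1.52e-102, and 6.07e-08 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, fell by 3.82 (SE 0.16, adjusted p = 1.71e-11), from 37.3 ± 4.72 to 2.68 ± 0.659 CPM. Also reduced were the sterol oxidase gene Sc4mol (-3.73), Nsdhl (-3.64), the lanosterol demethylase Cyp51 (-3.14), Idi1 (-4.75) and the squalene epoxidase Sqle (-4.97). Of 19 fatty acid synthesis genes 15 fell and 4 did not pass, with 18 falling when adjusted over the list alone (camera adjusted p = 1.44e-49, and 5.98e-05 with an estimated correlation). The desaturases Fads1 and Fads2 fell by 2.70 and 1.64, and Gpam, which starts glycerolipid synthesis, was at -0.65 (adjusted p = 0.0529). Among 10 genes of the SREBP processing machinery 4 fell, namely Srebf1 (-3.62), Insig1 (-2.65), Srebf2 (-0.97) and Scap itself (camera adjusted p = 6.66e-07, and 0.000786 with an estimated correlation). Since Scap is the deleted gene, part of this list's fall is set by the knockout, here and in Double LKO livers. The list was not tested without Scap. In SCAP LKO replicate 4 Srebf2 was at 20.4 CPM against 14.4 to 15.3 in the other 3. Without this replicate 23 of the cholesterol genes and 12 of the fatty acid synthesis genes passed.

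Beyond these groups, 4 of 29 fatty acid oxidation genes fell in SCAP LKO livers and 25 did not pass, with 1 rising and 5 falling when adjusted over the list alone. They included Cyp4a10 (-2.16), which has close relatives, the peroxisomal enzyme Ehhadh (-1.04), and Acaa1b (-0.94), whose call was lost without SCAP LKO replicate 4 (-0.77, adjusted p = 0.0599). The camera call of this list (adjusted p = 0.00774) was lost with an estimated correlation (adjusted p = 0.657) and without SCAP LKO replicate 4 (camera adjusted p = 0.268), and fry gave 0.31. In phospholipid metabolism Pcyt2 fell by 0.68 and Lpcat3 by 0.57, with 16 of 18 genes not passing (camera adjusted p = 0.135), and Lpcat3 was lost without replicate 3 or 4 (adjusted p = 0.0684 and 0.0772). Of 23 NRF2 and oxidative stress genes Gsta4 (0.63) and Prdx1 (0.37) rose and 21 did not pass (camera adjusted p = 0.000251, but 0.497 with an estimated correlation), and both calls were lost against the SCAP-floxed controls alone (adjusted p = 0.181 and 0.224). Macrophage and monocyte markers, of which 21 were measured, had a median of 0.35 and a camera adjusted p of 7.23e-05, against 0.657 with an estimated correlation. Without SCAP LKO replicate 4 the median was 0.19 and the camera call was lost (adjusted p = 0.0675).

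Other genes rose in SCAP LKO livers with no overlap between the groups. Enho, which encodes the secreted peptide adropin, rose by 1.47 (SE 0.19, adjusted p = 5.51e-05), from 14.3 ± 2.79 to 40.7 ± 4.32 CPM. The others were Dnaic1 (3.01), Mfsd7c (1.5), Slc16a5 (1.02), Hist1h1d (1.01), Zfp418 (0.99), Dynll1 (0.97), Spc24 (0.92), Cyp2c55 (0.96) and Mup20 (1.10), the last 2 from families that share reads. All of these but Enho missed the threshold against the 2 SCAP-floxed controls alone, with adjusted p from 0.0514 for Dnaic1 to 0.762 for Cyp2c55. Their log2 changes against these controls ran from 0.53 for Cyp2c55 to 3.34 for Dnaic1. In that setting 90 genes passed, 2 of them higher, and DESeq2 called 225. Mup17, a major urinary protein gene with near-identical copies, was at -4.50 (adjusted p = 0.0466), a call lost with the SCAP-floxed controls alone (-2.69, adjusted p = 0.606), with quality weights (adjusted p = 0.136) and without any one of the SCAP LKO replicates (adjusted p from 0.0945 to 0.169) or of the HDAC3-floxed or double-floxed controls (0.053 to 0.0788). It ranged from 111 to 1250 CPM among the control livers.

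Livers lacking both genes had the low sterol and fatty acid synthesis genes of SCAP loss together with raised lipid storage genes. All 24 cholesterol synthesis and uptake genes fell against control, with a median log2 change of -2.41, and Scd1 fell by 8.22 (SE 0.53, adjusted p = 3.81e-09), to 14.3 ± 2.79 CPM (n = 3). Gpd1 rose by 1.74 (SE 0.13, adjusted p = 2.62e-08), and Cidec and G0s2, which encode a lipid droplet protein and an inhibitor of triglyceride lipase, rose by 2.52 and 2.60. Cidec was at 69.2 CPM in library 2 against 11 and 12.7 in the others, and its change was 1.26 without library 2, still called. In all, 1669 genes differed from control, 908 higher and 761 lower (edgeR, adjusted p under 0.05), of which 353 changed at least 2-fold.

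All 24 cholesterol genes fell in Double LKO livers over the list alone as well (camera adjusted p = 1.21e-47, and 4.44e-06 with an estimated correlation). The log2 changes were -3.99 for Fdps, -3.97 for Sc4mol, -3.86 for Nsdhl, -2.45 for Lss, -5.81 for Idi1 and -4.35 for Sqle. Of 19 fatty acid synthesis genes 13 fell and 6 did not pass, 16 falling when adjusted over the list alone (camera adjusted p = 1.17e-18, and 0.0073 with an estimated correlation), with Fads1 at -3.67, Fads2 at -2.19 and the citrate carrier Slc25a1 at -1.08. Of 10 SREBP processing genes 4 fell, Insig1 by 3.03, Srebf1 by 2.98 and the deleted Scap among them, while Insig2 rose by 1.63 (camera adjusted p = 0.00342, and 0.0352 with an estimated correlation). Of 24 lipid droplet and triglyceride storage genes 11 rose, 1 fell and 12 did not pass, with 14 rising and 1 falling when adjusted over the list alone (camera adjusted p = 4.57e-06, and 0.033 with an estimated correlation), including Pnpla2 at 0.88. Of 29 fatty acid oxidation genes 9 rose, 1 fell and 19 did not pass, with 10 rising and 1 falling over the list alone. Acadm rose by 1.08, Cpt1b by 1.79 and Cpt2 by 0.53, the last lost against the 2 double-floxed controls alone (adjusted p = 0.209). This list's camera call (adjusted p = 0.00113) was lost with an estimated correlation (adjusted p = 0.527), and fry gave 0.0339.

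Some stress and xenobiotic genes rose as well in Double LKO livers. Of 23 NRF2 and oxidative stress genes 12 rose and 11 did not pass, 13 rising when adjusted over the list alone (camera adjusted p = 3.75e-08, but 0.066 with an estimated correlation), with the quinone reductase Nqo1 at 1.49, Gstm4 at 1.11, Gsta2 at 2.40 and Gstm3 at 3.08. Library 2 stood higher in this list, by a median log2 difference of 0.48 over libraries 3 and 4, and Gstm3 ranged from 149 to 1180 CPM. Of 17 genes of the constitutive androstane receptor and xenobiotic metabolism 8 rose, 1 fell and 8 did not pass (camera adjusted p = 1.13e-05, but 0.111 with an estimated correlation), with Cyp2c38 at 1.80, Cyp2c37 at 1.56 and Cyp2a5 at 1.35, all of families that share reads. Arntl rose by 2.17 and Clock by 0.74 while Per2 fell by 0.78 and Per3 by 0.81, and of 18 clock genes 3 rose and 5 fell (camera adjusted p = 0.376; Per2 missed the threshold with the double-floxed controls alone, adjusted p = 0.118). Of 23 acute phase genes 7 rose and 16 did not pass, with 11 rising when adjusted over the list alone, among them the ferroxidase Cp (0.63), Steap4 (0.91), Orm2 (2.78) and Orm3 (3.27), the last 2 being close relatives. Its camera call (adjusted p = 0.00335) was lost with an estimated correlation (adjusted p = 0.527), and fry gave 0.0914. Library 2 was at a median of 0.32 over the other 2 in these genes, and 3 acute phase genes passed without it. Steap4 (0.65, adjusted p = 0.0797) and Orm2 (1.11, adjusted p = 0.101) did not pass then. Cp was lost with the double-floxed controls alone (0.51, adjusted p = 0.0732). Cd14, a receptor of monocytes, was called at 2.28 (adjusted p = 0.0403), but was at -0.20 without library 2.

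The 10 highest changes without overlap of the libraries were in Gsta1 (4.81), Cyp2b9 (4.41), Tpm2 (3.56), Slc16a5 (3.35), Orm3, Tubb2a (3.15), Gstm3, the thyroxine-binding globulin gene Serpina7 (3.01), Acnat2 (2.66) and G0s2. Library 2 set much of the spread, since Gsta1 ranged from 7.78 to 109 and Tubb2a from 28 to 294 CPM in the Double LKO livers. Without library 2 the changes were 2.66 for Gsta1, 1.38 for Tubb2a and 1.48 for Gstm3, still called. Besides lipid synthesis genes, the most reduced were Aldoc, an aldolase (-4.51), Mfsd2a, a lysophospholipid transporter (-4.01), and Scara5 (-3.96). Mfsd2a and Scara5 also differed between control lines, with Mfsd2a at 81.2 CPM in HDAC3-floxed and 21.5 in double-floxed controls, and Scara5 was lost with the double-floxed controls alone (adjusted p = 0.164). With those 2 controls alone 714 genes passed.

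**Figure D2:**
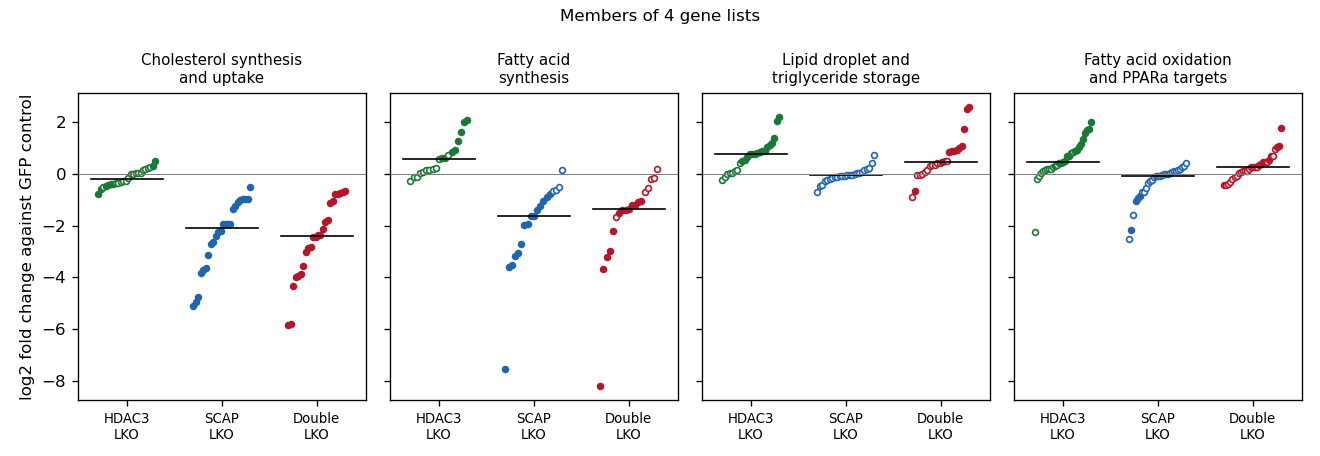
Log2 fold change against GFP control of each measured member of 4 gene lists in HDAC3 LKO, SCAP LKO and Double LKO livers. Filled points passed an adjusted p under 0.05 in edgeR, open points did not, and the line is the median of the list. All 24 cholesterol genes fell in SCAP LKO and Double LKO livers, and 16 of 24 lipid droplet genes rose in HDAC3 LKO and 11 in Double LKO livers.

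Double LKO and HDAC3 LKO livers were compared to ask what loss of SCAP added where HDAC3 was already absent. Genes of cholesterol and fatty acid synthesis were lower in the livers that lacked both. Scd1 fell by 10.3 on the log2 scale (SE 0.58, adjusted p = 7.54e-10), from 18300 ± 4820 (n = 4) to 14.3 ± 2.79 CPM (n = 3), and Fasn (-3.8) and Fdps (-4.02) fell too. Hdac3 itself differed by 0.24 (adjusted p = 0.516) and Scap fell by 1.58. In all, 157 genes differed, 13 higher and 144 lower in Double LKO (edgeR, adjusted p under 0.05), of which 101 changed at least 2-fold.

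Against HDAC3 LKO, all 24 cholesterol genes fell in Double LKO livers, also over the list alone (camera adjusted p = 3.35e-92, and 2.61e-09 with an estimated correlation), and 15 of 19 fatty acid synthesis genes fell, 17 over the list alone (6.4e-52 and 4.95e-05). The log2 differences were -3.52 for Nsdhl, -3.28 for Cyp51, -3.52 for Sc4mol, -5.45 for Idi1, -3.82 for Fads1 and -2.82 for Fads2. Of 10 SREBP processing genes 4 fell, namely the deleted Scap, Srebf1 (-3.06), Insig1 (-3.02) and Srebf2 (-0.61). For this list, which includes Scap, the camera adjusted p was 2.62e-06, and 0.00136 with an estimated correlation. The call of Srebf2 was lost without any one of several libraries, for example library 3 (adjusted p = 0.125). Of 29 fatty acid oxidation genes 4 fell, 5 over the list alone, among them Ehhadh (-1.43), Acaa1b (-1.11) and Pdk4 (-1.31). This list's camera call (adjusted p = 5.43e-05) was lost with an estimated correlation (adjusted p = 0.363; fry 0.0987), and Acaa1b and Pdk4 were lost without library 2 (adjusted p = 0.072 and 0.0533). Of 20 lipoprotein and sterol export genes Pltp, the phospholipid transfer protein, fell by 1.88 and Apoc2 by 0.48, with 3 falling over the list alone (camera adjusted p = 9.27e-05, but 0.243 with an estimated correlation and 0.0604 without library 2; Apoc2 was lost without library 2, adjusted p = 0.0704). Of 24 lipid droplet genes 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0697). The steroid hydroxylase Cyp17a1 fell by 2.76 (SE 0.41, adjusted p = 0.000447), to 3.23 ± 1.22 from 24.1 ± 12.6 CPM, and Cyp4a12b, a close relative of Cyp4a12a, was at -2.23 (SE 0.32, adjusted p = 0.000222). Both calls were lost when every knockout was set against its own floxed controls (adjusted p = 0.493 and 0.375). The endothelial marker Lyve1 fell by 1.13, a call lost without library 4 (adjusted p = 0.106), beside 15 of 16 endothelial markers that did not pass. By camera, endothelial (median -0.19, adjusted p = 0.00103), hepatocyte (-0.24, 0.000614) and erythroid markers (-0.76, 0.00012) were lower as lists. With an estimated correlation these calls were lost (adjusted p = 0.363, 0.468 and 0.243), and without library 2 the first 2 were lost in camera too (0.0817 and 0.991).

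The genes highest in Double LKO against HDAC3 LKO livers were Cyp2b9 (3.45), Id3 (1.22), Enho (1.20), the haptoglobin gene Hp (0.89) and Lrrc42 (0.73), and Hp was lost without library 2 (0.69, adjusted p = 0.167). Each of these 5 was lost when every knockout was set against its own floxed controls, with adjusted p from 0.114 for Enho to 0.83 for Id3. So were Mfsd2a (-4.42) and Rpl29 (-5.47; adjusted p = 0.316 and 0.978 there), and Rpl29 differed between control lines from 23.5 CPM in HDAC3-floxed to 0.385 in SCAP-floxed livers. In that setting 67 genes passed, with only the 2 knockout groups in the fit 99, and with DESeq2 237.

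Double LKO and SCAP LKO livers were compared to ask what loss of HDAC3 added where SCAP was already absent. Of the measured genes of lipid storage 9 of 24 were higher in the livers that lacked both, and of fatty acid oxidation 11 of 29. With an estimated correlation the second list did not pass (camera adjusted p = 0.238) and the first did (0.026), but not without library 2 (0.0855). Plin2 rose by 1.55 on the log2 scale (SE 0.21, adjusted p = 0.000186), Gpd1 by 1.32 (SE 0.15, adjusted p = 3.18e-05), Pnpla2 by 0.95 and Cidec by 2.75, the last at 1.48 without library 2, still called. With genotype-matched controls the calls of Plin2 (1.22, adjusted p = 0.126), Pnpla2 (0.76, adjusted p = 0.092) and Cidec (2.44, adjusted p = 0.409) were lost. Hdac3 fell by 1.78 and Scap differed by -0.10 (adjusted p = 0.729). In all, 959 genes differed, 598 higher and 361 lower in Double LKO (edgeR, adjusted p under 0.05), of which 201 changed at least 2-fold.

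Against SCAP LKO, 9 of 24 lipid droplet and triglyceride storage genes rose in Double LKO livers and 15 did not pass, 14 rising when adjusted over the list alone (camera adjusted p = 9.43e-08, and 0.026 with an estimated correlation, which became 0.0855 without library 2). Of 29 fatty acid oxidation genes 11 rose and 1 fell, 13 and 1 over the list alone, with Ehhadh at 1.29, Cpt1b at 1.80, Acaa1b at 1.40 and Cyp4a10 at 2.86, from 79.2 ± 45.5 (n = 4) to 570 ± 293 CPM (n = 3). This camera call (adjusted p = 3.34e-08) was lost with an estimated correlation (adjusted p = 0.238), and fry gave 0.00857. Fatty acid synthesis genes went both ways, 2 rising and 3 falling of 19 (camera adjusted p = 0.789), with Acacb at 2.34 and Fads1 at -0.97, Fads2 at -0.55 and Slc25a1 at -0.31. Slc25a1 was lost without any one of the Double LKO libraries (adjusted p from 0.062 to 0.106). Fads2 was lost without library 3 or 4 (adjusted p = 0.0936 and 0.105), and Fads1 with genotype-matched controls (-0.98, adjusted p = 0.214). Of 24 cholesterol genes 1 rose and 1 fell, the latter being Lss (-0.52) (camera adjusted p = 0.274). The call of Lss was lost without library 4 (-0.37, adjusted p = 0.131) or SCAP LKO replicate 4 (-0.45, adjusted p = 0.0617). Insig2 rose and was the 1 called gene among 10 of the SREBP processing machinery. Of 23 NRF2 genes 8 rose, with Nqo1 at 1.30, Gstm4 at 0.92, Gsta2 at 1.69 and Gstm3 at 2.44, the last at 0.84 without library 2 (camera adjusted p = 0.00029, but 0.243 with an estimated correlation; 5 passed without library 2). Arntl rose by 2.10 and Clock by 0.64, with 2 rising and 2 falling of 18 clock genes (camera adjusted p = 0.591). Of 23 acute phase genes 6 rose, with Steap4 at 1.25, Cp at 0.54, Orm2 at 2.47 and Orm3 at 5.53 (camera adjusted p = 5.19e-06, but 0.243 with an estimated correlation), and Orm2 was lost without library 2 (0.79, adjusted p = 0.344).

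Also among the highest in Double LKO against SCAP LKO livers were Tubb2a (2.94, but 1.16 without library 2) and Cyp2b9 (2.69), and the lowest were Gpr110 (-2.43), Hsd3b5 (-2.28), Cspg5 (-2.25), Pcp4l1 (-2.12) and Col27a1 (-2.10). When each knockout was set against its own floxed controls, 65 genes passed, 73.8% of them higher against 62.4% of the 959, and calls such as Plin2 (1.22, adjusted p = 0.126), Arntl (1.68, adjusted p = 0.345) and Col27a1 (-1.40, adjusted p = 0.15) were lost. With only the 2 knockout groups in the fit 519 genes passed, and Hsd3b5 (adjusted p = 0.16) and Tubb2a (0.0631) were lost. Without library 3 Cspg5 (adjusted p = 0.0626), Hsd3b5 (-2.04, 0.113) and Cyp2b9 (2.35, 0.079) were lost. Hsd3b5 and Cyp2b9 were also lost without SCAP LKO replicate 1, 2 or 3 (adjusted p from 0.0521 to 0.0769). Hsd3b5 did not pass with DESeq2 (adjusted p = 0.0666), nor Cyp2b9 with quality weights (0.0538).

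Whether the double knockout differed from the sum of the single knockouts was tested directly. All knockout groups received Cre and the controls GFP. An effect of Cre itself would also shift this contrast and cannot be told apart. No gene passed with edgeR. Of 12009 tested genes 601 had an unadjusted p under 0.05, about as many as chance alone gives. DESeq2 called 9 of the 1314 genes it gave an adjusted p. The fit was not tested on simulated changes in this contrast, so how large a deviation it would miss is not known. Scd1, for example, was not called here but lay below the sum. It averaged 18300 CPM in HDAC3 LKO against 4340 in control livers, but 14.3 in Double LKO against 22.8 in SCAP LKO livers. The absence of calls therefore does not show that the 2 losses add up for every gene. Hdac3 deviated from the sum by 0.17 (SE 0.16, adjusted p = 0.973) and Scap by -0.37 (SE 0.17, adjusted p = 0.969). By camera, fatty acid synthesis genes lay below the sum (median -0.26, adjusted p = 7.58e-06) and acute phase genes above it (median 0.56, adjusted p = 2.68e-12). Both calls were lost with an estimated correlation (adjusted p = 0.262 for each), and fry gave 0.289 for each.

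Of the genes called against control in both HDAC3 LKO and SCAP LKO livers, 15 were higher in both, 11 lower in both and 30 opposite. Both groups received Cre, so an effect of Cre itself would be present in both. So few calls shared in direction, of 1666 in HDAC3 LKO and 143 in SCAP LKO, argue against Cre as the source of most HDAC3 LKO calls. Independent lists as long as the 2 lists of calls would share 2.4 higher and 6.7 lower genes. Simulated groups without changed genes, set against shared simulated controls, shared 0 in either direction in 20 simulations. Without changed genes hardly any calls arise, so this 0 does not show how many shared calls common controls add. With the controls split into separate parts for the 2 comparisons, a median of 3 genes were higher in both, 4 lower in both and 21.5 opposite over 8 splits. Each comparison then had fewer control livers, and its calls fell as well, to medians of 972.5 in HDAC3 LKO and 104 in SCAP LKO. Part of the drop may therefore be lost power. The covariance of the fold changes across genes was 0.008, lower than the 0.0165 that shared controls alone gave (difference -0.0085), with r of 0.06 against 0.373. HDAC3 LKO and Double LKO shared 561 higher and 360 lower genes, against 71.5 and 45.6 for independent lists, with 20 opposite. SCAP LKO and Double LKO shared 19 higher and 87 lower genes, against 2.3 and 7.1, with 2 opposite. The covariances exceeded those of shared controls by 0.0964 and 0.0697. Genes are not independent replicates, and part of each excess may come from the shared controls.

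In the authors' deposited table, 1278 genes had a false discovery rate under 0.05 in HDAC3 LKO, 757 higher and 521 lower, and 1139 of them were also called here. For SCAP LKO the authors' deposited table called 231 genes, 36 higher and 195 lower, of which 129 were also called here. For Double LKO it called 674, 449 higher and 225 lower, of which 632 were also called here. All shared genes had the same sign in the authors' deposited table and here.

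Most HDAC3 peaks listed for livers given HA-nSREBP1c were also listed for GFP livers. The deposited lists held 18471 HDAC3 peaks for GFP livers, 13798 for HA-nSREBP1c livers and 7701 HA peaks for HA-nSREBP1c livers. Each group has 1 list with no replicate values, so these comparisons have no replicate check, a difference in list length is not a measure of binding, and the 95% exact binomial intervals below cover counting error only. Of the HDAC3 peaks of GFP livers, 12009 (65%, interval 64.3 to 65.7) overlapped one of HA-nSREBP1c livers by at least 1 bp, and of the HDAC3 peaks of HA-nSREBP1c livers 11979 (86.8%, 86.2 to 87.4) overlapped one of GFP livers. Randomly placed peaks gave a mean of 43.0 and at most 59 overlaps for the first of these.

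Many peaks of nuclear SREBP1c overlapped HDAC3 peaks. Of the HA peaks, 4300 (55.8%, interval 54.7 to 57) overlapped an HDAC3 peak of GFP livers and 4076 (52.9%, 51.8 to 54) one of HA-nSREBP1c livers, against 23.9 and 17.2 with randomly placed peaks. Random peaks, here and for the HDAC3 lists, were placed anywhere along each chromosome. They are a low bar for any ChIP-seq lists, so the excess does not show a specific link between SREBP1c and HDAC3. HDAC3 was in both conditions at 3581 HA peaks (46.5%), in GFP livers alone at 719 (9.3%) and in HA-nSREBP1c livers alone at 495 (6.4%), and 2906 (37.7%, 36.7 to 38.8) had no HDAC3 peak. Seen from HDAC3, 29.9% (interval 29.1 to 30.8) of 12009 peaks found in both conditions overlapped an HA peak, 26.4% (24.4 to 28.5) of 1819 found in HA-nSREBP1c livers alone, and 11% (10.3 to 11.8) of 6462 found in GFP livers alone.

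**Figure D3:**
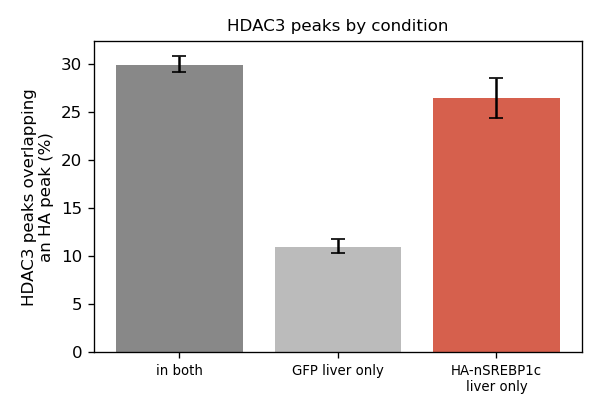
Percent of HDAC3 ChIP-seq peaks that overlap an HA-nSREBP1c peak, for peaks found in both conditions, in GFP livers alone and in HA-nSREBP1c livers alone. Bars start at 0 and error bars are 95% exact binomial intervals, which cover counting error only. The share was 29.9%, 11% and 26.4%.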

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

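The tests of lists without Double LKO library 2 or SCAP LKO replicate 4, of the Scap segment, of the Scap level, of macrophage and acute phase genes, of Y-linked genes and of the male to female shift were chosen only after the result was seen.

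Control livers of the floxed lines differed: between controls with a floxed Scap allele (SCAP-floxed and double-floxed) and HDAC3-floxed controls 50 of 11713 genes were called (1124 at an unadjusted p under 0.05 in edgeR), among them Rpl29 (log2 difference -5.43) and Igfbp1 (-2.88). Depth is argued against, since 46 of the 50 were still called after every control library was thinned to the smallest. A segment of chromosome carried along with the floxed Scap allele may account for 13 genes, as 6.5% of the 200 tested genes nearest Scap were called against 0.32% of 11430 others (Fisher's exact test, two-sided p = 1.58e-12), and the other 37 are left without an account. Among the 37, G6pc (-1.09), Tat (-1.07), Saa1 (-1.78) and Saa4 (-0.85) were lower with a floxed Scap allele, while others such as Acot3 (1.87) and Csad (1.08) were higher. Some set mainly the double-floxed controls apart. Gal3st1 averaged 9.73 CPM in these, against 1.02 in SCAP-floxed and 0.657 in HDAC3-floxed controls, and Tbc1d10a 1.92 against 10.6 and 12.8. A lower level of Scap from the allele stays open, with Scap at -0.34 (SE 0.11, adjusted p = 0.328) and cholesterol genes at a median of -0.12, as does an untested biological difference between the lines. Genes that differ between these lines make up 11 of the calls in HDAC3 LKO, 1 in SCAP LKO and 10 in Double LKO against control. They make up 4 of the 157 calls in Double LKO against HDAC3 LKO and 1 of the 959 against SCAP LKO. The test between lines rested on few control livers, so these counts may understate how far line differences enter the calls.

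Double LKO library 2 stood apart from libraries 3 and 4, at 45.8 on the second component against a mean of 5.1. Its low depth is argued against, since the other libraries thinned to its depth reached at most 8.2. RNA of macrophages or blood cells and an acute phase response in that mouse stay open, as macrophage and acute phase genes both had a median log2 difference of 0.32 (bootstrap SE 0.29 for each, interquartile ranges 0.10 to 1.16 and -0.36 to 0.93). Erythroid markers were not raised in this library (median -0.10), while cell cycle (0.82) and unfolded protein and integrated stress response genes (0.61) were higher and male-biased genes (-1.31) and hepatocyte markers (-0.76) lower. A varying response of individual mice to the double knockout was not tested and also stays open.

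Of 8 female-biased liver genes 4 rose in HDAC3 LKO livers, a list call lost with an estimated correlation (adjusted p = 0.169), and Cyp2a4 among them was not called without HDAC3 LKO replicate 2 (0.84, adjusted p = 0.676). Male-biased genes went both ways, with 2 of 14 rising and 3 falling. Female mice are argued against, since the lowest ratio of Y-linked genes to the control mean was 0.92 among HDAC3 LKO libraries. A general shift from the male to the female pattern may be part of it and stays open: 2 male-biased genes rose, Elovl3 (2.08) and Cyp4a12b (1.03), but Cyp4a12b was not called with genotype-matched controls (0.70, adjusted p = 0.197). A direct effect of HDAC3 on these genes was not tested.

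Other splits of the same libraries were refitted to ask whether chance could give as many calls. For HDAC3 LKO, 1 of 100 splits, the real one, gave as many as 1666, and the highest other gave 417. For SCAP LKO it was 1 of 100 (143, highest other 36), for Double LKO 1 of 84 (1669, highest other 46), for Double LKO against HDAC3 LKO 1 of 35 (157, highest other 24) and against SCAP LKO 1 of 35 (959, highest other 126). For HDAC3 LKO and SCAP LKO 100 of 210 possible splits were run. The other splits mix livers of both groups, which puts the difference between groups into the spread within them and favours the real split. These ranks therefore do not exclude chance. For the non-additive contrast the real count is 0 (edgeR, with 601 genes at an unadjusted p under 0.05 and 9 called by DESeq2), so each of the 40 splits had to give as many (40 of 40, highest other 0) and they say nothing about chance.

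Of 265 groups of 4 to 6 libraries, 21 (7.9%) had 1 library far from the others, where chance gives about 1 in 20 groups. The value is the gap to the nearest other library over the whole range. In HDAC3 LKO replicate 2 these were Abcb4 (0.948; 509 CPM against 685 to 697), Tbl1xr1 (0.903), Gpd1 (0.886), Cyp51 (0.884; 125 against 180 to 189), Fads2 (0.866; 865 against 528 to 564), Lyve1 (0.843; 35.8 against 17 to 19.1), Mvk (0.834) and Sc4mol (0.834; 106 against 145 to 155). In HDAC3 LKO replicate 3 they were Gstm2 (0.858; 34.4 against 48.3 to 51.1) and Acot3 (0.848; 18.3 against 61.6 to 76.6), and in replicate 4 Abcc4 (0.876; 61 against 29.9 to 32.6). In SCAP LKO replicate 4 they were Acacb (0.869; 13.6 against 5.98 to 6.67), Nqo1 (0.856; 23 against 14.5 to 15.5), Acaa1b (0.842; 226 against 394 to 437) and Srebf2 (0.837). Among controls they were Fdps (0.808; 46.8 against 34.5 to 36.6), Serpina7 (0.663; 14 against 45.9 to 83.6), Elovl3 (0.643; 43.6 against 18.8 to 25.4) and Enho (0.635; 19.8 against 12.3 to 14.6) in HDAC3-floxed library 1, Steap4 (0.757; 353 against 179 to 211) in HDAC3-floxed library 2 and Insig1 (0.684; 478 against 238 to 297) in SCAP-floxed library 1.

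For 8 lists the double knockout deviated from the sum of the single ones by camera. Either an effect of HDAC3 loss that differs with SCAP or an effect of Cre itself could give this. The medians were -0.26 for fatty acid synthesis (adjusted p = 7.58e-06), 0.17 for the NCoR and HDAC complex (0.0311), 0.56 for acute phase (2.68e-12), -0.24 for hepatocyte markers (0.000925), -0.34 for macrophage markers (0.000321), -0.17 for endothelial markers (0.0222), -0.88 for erythroid markers (0.000586) and -0.30 for male-biased genes (0.0117). With an estimated correlation the adjusted p was at least 0.262 and with fry at least 0.289 for each of these lists, so every call was lost. Without Double LKO library 2 the camera calls of hepatocyte markers (-0.01, adjusted p = 0.887), endothelial markers (-0.07, 0.354) and male-biased genes (0.03, 0.887) were lost as well. Without SCAP LKO replicate 4 those of the NCoR and HDAC complex (0.13, adjusted p = 0.0513) and of macrophage markers (-0.20, 0.0576) were lost.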

How the results depend on the processing

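The voom fit with library quality weights, the fit of numbered libraries without a block and the list counts without single libraries were tests chosen only after the result was seen. Counts of calls are compared with 1666 (HDAC3 LKO), 143 (SCAP LKO), 1669 (Double LKO), 157 (Double against HDAC3 LKO), 959 (Double against SCAP LKO) and 0 (non-additive, edgeR, with 601 at an unadjusted p under 0.05). With genotype-matched controls these were 839, 90, 714, 67, 65 and 0. In that setting each knockout has 2 control libraries, and comparisons between knockouts are differences of matched effects, to which the controls add their own spread. With only the groups compared they were 1839, 197, 1119, 99 and 519. For RLE normalization, no filter, DESeq2 and quality weights, counts within 1.5 times of those compared are not given. DESeq2 gave 225 for SCAP LKO, 237 for Double against HDAC3 LKO and 9 for the non-additive contrast, which had 2 with no filter on low counts. Quality weights gave 234 for SCAP LKO, 2874 for Double LKO, 509 and 1967 for Double against HDAC3 and SCAP LKO and 6 for the non-additive contrast, with 0.273 the weight of Double LKO library 2. Leaving out each library gave 1086 to 1762, 102 to 166, 1211 to 1632, 112 to 187, 679 to 1077 and 0 to 2, and HDAC3 LKO replicate 4 alone moved a count above 0 by over 1.5 times (1086 without it), while the non-additive count became 1 without Double LKO library 2 or HDAC3 LKO replicate 2 and 2 without SCAP LKO replicate 4. The cause was not tested.

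The replicate block on numbered libraries gave 822 genes for HDAC3 LKO and 250 for SCAP LKO, and the same libraries with no block 1079 and 261. Correlations over all genes gave no sign that the numbers pair the mice, though a pairing that affects few genes could be missed. Of 8 same-numbered pairs 1 had a correlation over 0.1 (-0.097 to 0.108), and 24 other pairs ranged from -0.128 to 0.202. No paired analysis was possible because the Double LKO columns could not be tied to numbered samples, for the 3 Double LKO comparisons and the non-additive contrast.

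The share of higher calls moved by over 10 points in SCAP LKO (21.7%, but 2.2% with matched controls), Double against HDAC3 LKO (8.3%, but 28.3% with quality weights, 20.9% without library 3 and 19.2% without library 4) and Double against SCAP LKO (62.4%, but 73.8% with matched controls and 72.6% with only the groups compared). Gene lists called fell from 50 of 145 to 12 with an estimated correlation, and fry called 36. Genes called in the same direction in HDAC3 LKO and SCAP LKO fell from 26 to a median of 7 (5 to 8) with split controls. All calls fell in that setting too, from 1666 to a median of 972.5 in HDAC3 LKO and from 143 to 104 in SCAP LKO. Lost power and shared controls cannot be told apart there. A reciprocal overlap of 50% gave 54.7% for 55.8% and 51.8% for 52.9% of HA peaks. Reversed were Scap in Double against SCAP LKO (-0.10, but 0.06 with matched controls), Scap in the non-additive contrast (-0.37, but 0.01 with matched controls) and Cd14 in Double LKO (2.28, but -0.18 with quality weights and -0.20 without library 2, against 2.96 without library 4); the cause was not tested.

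Of 220 results of single genes, some of them not used in the text, all kept their direction and side of the threshold with RLE normalization, 217 with no filter on low counts, 212 with quality weights and 152 with matched controls, where 65 no longer passed. With DESeq2 209 of 213 did, with only the groups compared 198 of 218, and with the replicate block 88 of 102. Without Double LKO library 2 it was 108 of 118, and without SCAP LKO replicate 4, 59 of 71. In simulated data 30.6 to 48.4% of genes changed 1.5-fold were called at these depths, so small changes are often missed.

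Alternatives for normalized values and for authors' comparisons alone do not apply to a table of counts. The higher-scoring part of the peaks, the top-scoring peaks and genes near peaks were not run, since the lists carry no scores and no annotation of mm9 was used here.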

Other observations

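The tests of lists without Double LKO library 2 or SCAP LKO replicate 4 were chosen only after the result was seen.

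Some genes of bile acids and of phospholipids rose with loss of HDAC3. Of 18 bile acid genes 7 rose, 2 fell and 9 did not pass in HDAC3 LKO livers, with 8 rising and 2 falling when adjusted over the list alone (the list did not pass, camera adjusted p = 0.0517, and 0.629 with an estimated correlation), among them the exporters Abcc4 (1.79), Abcb11 (0.80) and Abcb4 (0.77) and the sterol hydroxylase Cyp27a1 (0.71). In SCAP LKO livers 1 of them fell, and in Double LKO livers 3 rose and 2 fell (camera adjusted p = 0.292 and 0.97). Of 18 phospholipid genes 7 rose in HDAC3 LKO and 8 over the list alone, a call lost with an estimated correlation (camera adjusted p = 0.000686, and 0.169), and 4 rose and 1 fell in Double LKO livers (camera adjusted p = 0.0521). Of 8 female-biased genes 4 rose in HDAC3 LKO and 4 in Double LKO, 6 over the list alone in each, with camera calls (adjusted p = 0.00275 and 0.00113) lost with an estimated correlation (adjusted p = 0.169 and 0.066). Cyp3a44 rose by 1.01 in HDAC3 LKO livers, and Cyp2a4 was called at 3.59 (adjusted p = 0.0407) but was at 0.84 (adjusted p = 0.676) without HDAC3 LKO replicate 2. Of 14 male-biased genes 2 rose and 3 fell in HDAC3 LKO (Slco1a1 by 1.05), and 1 rose and 4 fell in Double LKO livers (camera adjusted p = 0.236 and 0.00339, the latter 0.527 with an estimated correlation and 0.0848 in camera without library 2).

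Other groups changed in few genes. In HDAC3 LKO livers 4 of 20 lipoprotein genes rose and 1 fell (camera adjusted p = 0.0269, but 0.629 with an estimated correlation), 4 of 26 gluconeogenesis and glycolysis genes rose and 2 fell (0.224), 2 of 19 sphingolipid genes rose and 1 fell (0.557), 3 of 20 p53 and apoptosis genes rose (0.112), and 1 rose and 2 fell of 23 genes of the unfolded protein and integrated stress response (0.254). In the acute phase list 1 rose and 2 fell (0.509; its median is -0.10 and its mean 0.05), in cell cycle genes 1 rose and 1 fell of 19 (0.9), in inflammatory cytokine genes 2 fell of 13 (0.862), and in hepatocyte markers 2 rose and 2 fell of 22 (0.423). Of markers of other cells, 1 of 7 cholangiocyte and 1 of 6 erythroid genes fell (0.509 and 0.472). Stellate, endothelial and fetal markers had adjusted p of 0.112, 0.293 and 0.862 in camera, and macrophage markers 0.199. The lymphocyte and neutrophil lists had 1 tested gene each, at log2 changes of 0.07 and -0.43. Y-linked genes had a median of -0.10 in HDAC3 LKO (camera adjusted p = 0.443), and in Double LKO livers Uty (-0.40) and Kdm5d (-0.38) fell (camera adjusted p = 0.0164, but 0.066 with an estimated correlation), with Kdm5d not called with matched controls (-0.22, adjusted p = 0.441).

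The remaining camera calls of lists were all lost with an estimated correlation, whose adjusted p is given after each. In SCAP LKO livers against control they were lipoprotein genes (lower, 0.0072 and 0.657) and acute phase genes (lower, 0.0387 and 0.693), the first also lost in camera without SCAP LKO replicate 4 (0.0661). In Double LKO against HDAC3 LKO livers they were acute phase (higher, 7.59e-07 and 0.243), bile acid (lower, 0.00528 and 0.363), gluconeogenesis and glycolysis (lower, 0.0144 and 0.447), male-biased (lower, 0.0144 and 0.495), NRF2 (higher, 0.0172 and 0.468) and Y-linked genes (lower, 0.0172 and 0.132). Of these, without library 2 camera no longer called bile acid (0.504), gluconeogenesis and glycolysis (0.822), NRF2 (0.626) or male-biased genes (0.822), and the median of the last went from -0.11 to 0.20. In Double LKO against SCAP LKO livers they were xenobiotic metabolism (higher, 4.88e-05 and 0.238), male-biased (lower, 0.00305 and 0.519), phospholipid (higher, 0.00317 and 0.238), female-biased (higher, 0.00462 and 0.238) and erythroid genes (lower, 0.0473 and 0.582). The male-biased call was also lost in camera without library 2 (0.108, with a median of -0.29 against -0.64).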
